A study of Mus musculus with 21 samples.

How the data were processed

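RNA sequencing was done on 21 mouse skin samples in 5 groups. Per the labels' protocols, 8-week-old BALB/c recipients were irradiated with 700 cGy and given marrow from BALB/c donors (syngeneic) or B10.D2 donors (allogeneic), which leads to a sclerodermatous chronic graft-versus-host disease. Treatment began on day 21 and skin was taken at week 7. Antibodies were injected intraperitoneally with a first dose of 20 mg/kg and later doses of 10 mg/kg. For nintedanib the protocol gives 50 mg/kg by mouth each day, while the series' design text gives intraperitoneal injection for 4 weeks for every allogeneic group, so its route is uncertain here. RNA came from a piece of skin 3 mm in diameter, 1 μg was used per library, and poly-A RNA was made into libraries with a kit that does not mark strand. Reads from a gene and an overlapping or antisense gene can therefore not be told apart.

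The deposited values are whole-number counts of reads per gene symbol, which the authors made, per the submitters' processing notes, with FastQC, Trimmomatic, STAR and featureCounts on the GRCm39 build. Their versions and settings and the gene annotation are not given in the sources used here. The counts come in 2 sets that were counted with different gene names: 12 libraries (syngeneic isotype, allogeneic isotype and anti-IL1RAP) in the first counting run and 9 (allogeneic water and nintedanib) in the second. Of 64050 symbols, 21830 had counts in both runs, 12094 only in the first and 6185 only in the second. The 13 mitochondrial protein genes, for example, had counts only under mt- names in the first run and only under other names in the second. No coordinates are printed, since the reference annotation used here (only to find genes whose exons overlap) is of an older build.

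Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr at a minimum count of 10, which left 20462, libraries were scaled with TMM factors, and all 21 libraries entered 1 quasi-likelihood fit (glmQLFit and glmQLFTest) with a mean per group. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed, and each log2 fold change is given with its SE. CPM values are TMM-scaled, as mean ± SD over the libraries of a group. The replicates are separate samples per the labels, which do not say that each is a separate mouse, so p-values rest on the spread between samples. That spread was estimated over all 21 libraries and not over the groups compared alone. For a group more variable than the others, SEs and p-values may therefore be too low. A gene at 0 in every library of a group has a fold change given as a bound against 3 counts over that group. Such bounds cover counting error only.

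Gene lists for pathways, cell types and RNA quality, 33 in all, were fixed before the data were examined, as were the main tests, the rule for named genes and a set of alternative settings. Lists were tested on log2 CPM (prior count 2) with camera in limma 3.58.1 at its preset correlation of 0.01, again with an estimated correlation, and with fry. Named genes were the 6 largest called changes in each direction that reached 1 CPM and did not overlap between groups (predicted genes and clone names left out), up to 4 members with the lowest p of each list described, and 16 genes given whether called or not: Il1rap, Il1a, Il1b, Il33, Il36a, Il36g, Il1rn, Il6, Cxcl1, Col1a1, Col1a2, Col3a1, Fn1, Acta2, Pdgfra and Pdgfrb. Of the members picked by p, 2 genes are not reported here. Where no gene passed, the 3 lowest p per direction were named. A disease score was the mean log2 CPM of up to 200 genes higher and 200 genes lower in the allogeneic control group that the treatment comparison did not use, against syngeneic skin, with an exact 2-sided permutation test.

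The calculations were checked on simulated counts with known changes. Of 100 genes changed 4-fold, 84, 82 and 89 were recovered for the comparisons of allogeneic with syngeneic isotype (19204 genes), anti-IL1RAP with isotype (19265 genes) and nintedanib with water (16989 genes). Of 100 genes changed 2-fold, 40, 45 and 53 were recovered. False calls numbered 6, 3 and 5. A gene's simulated spread was the same in all groups, which may not hold for the real ones. Alternatives included RLE size factors, no filter, only the groups compared, a replicate block, DESeq2 1.42.0, both allogeneic controls together, the libraries with or without a note on 2 sequencing lanes, and leaving out each library in turn. Alternatives chosen after seeing the data used only symbols present in both runs, only libraries of 1 run, skeletal muscle or hair follicle content as a covariate, and pairs of nintedanib libraries left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.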

Results

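The transcriptome of mouse skin was measured in 21 libraries of a transplantation model of sclerodermatous chronic graft-versus-host disease, in which donor immune cells attack the skin of the recipient. Syngeneic recipients given an isotype antibody (4 libraries) had marrow from donors of their own strain. Allogeneic recipients received the isotype antibody (4 libraries), mCAN10, an antibody against the IL-1 receptor accessory protein IL1RAP (4 libraries), water (4 libraries), or nintedanib, an inhibitor of the PDGF, FGF and VEGF receptor kinases (5 libraries). IL1RAP is the co-receptor through which IL-1, IL-33 and IL-36 signal. Total counts per library ranged from 17130260 to 32899210. Group means ± SD were 26201250 ± 4644930 for syngeneic isotype, 21250780 ± 2940237 for allogeneic isotype, 23785440 ± 4102248 for anti-IL1RAP, 17714050 ± 264968 for allogeneic water and 18083390 ± 786862 for nintedanib. The sex of the animals is not given in the sources used here.

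The 12 syngeneic, allogeneic isotype and anti-IL1RAP libraries and the 9 water and nintedanib libraries were counted with different gene names. Over symbols with counts in both counting runs, the first principal component held 44.7% of the variance and separated the 2 runs, while the second held 17.2% and placed syngeneic libraries between -61.0 and -50.0 and allogeneic isotype libraries between 69.2 and 92.0. The anti-IL1RAP libraries lay between them, from -29.9 to 12.5. Each treatment was therefore compared with the control of its own run. Gene values are log2 fold changes ± SE with edgeR's adjusted p, and list tests give camera's adjusted p.

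The comparison of allogeneic with syngeneic recipients, both given isotype antibody, asks how skin differs in the disease. Donor strain (B10.D2 against BALB/c) parts the same groups. Differences between donor cells of the 2 strains therefore cannot be told apart from disease. Y-linked counts also part these groups (4.40 ± 1.63 CPM in syngeneic and 0 in allogeneic isotype libraries), as described below. Of the interferon-stimulated genes 30 of 33 rose, as did 14 of 16 MHC class I, 9 of 11 MHC class II, 12 of 18 T cell, 11 of 17 cytotoxic and 10 of 20 macrophage genes. In the epidermis 9 of 13 activated and 13 of 20 differentiated keratinocyte genes rose, and some sebaceous gland, fibroblast and nerve genes fell. Isg15, an interferon-induced ubiquitin-like modifier, went from 11.9 ± 5.42 to 193 ± 20.6 CPM, and Krt16, a keratin of stressed epidermis, from 20.3 ± 4.09 to 2386 ± 1118 CPM (SD, n = 4 in each group). Of 20462 genes tested, 4621 changed, 2821 higher and 1800 lower in allogeneic skin, and 20 of 33 gene lists shifted, 13 up and 7 down, none of them with an estimated correlation (lowest adjusted p = 0.416). The largest increases were of the chitinase-like genes Chil3 (at least 2522-fold higher) and Chil4 (at least 780-fold higher), the steroid reductase Akr1d1 (at least 275-fold), the interferon-inducible Ifi213 (at least 282-fold), and the cystatin-type protease inhibitors Stfa2 (11.92 ± 1.64, adjusted p = 0.000112) and Cstdc6 (10.60 ± 1.47, adjusted p = 0.000115). Several of these belong to families of near-identical genes whose reads may be split between members, so the assignment to Chil3 or Chil4, Ifi213, Stfa2 and Cstdc6 is uncertain. The largest decreases were of the neuropeptide gene Cartpt (at least 142-fold lower), the chloride channel subunit Bsnd (at least 96.1-fold lower), Nnat (-7.58 ± 1.58), the relaxin receptor Rxfp1 (-7.35 ± 1.26), Hamp2 (-6.17 ± 0.70) and Cyp2g1 (-5.98 ± 1.15), with adjusted p up to 0.00232.

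Among interferon-stimulated genes, 30 of 33 rose and 3 did not pass the test (33 rose adjusted over the list alone; adjusted p = 1.60e-21). Isg15 rose by 4.02 ± 0.43 (adjusted p = 2.36e-05), the T cell attractant Cxcl11 by 6.19 ± 0.80 (adjusted p = 7.66e-05), the signal transducer Stat2 by 2.43 ± 0.30 and the RNA sensor Oas1a by 3.33 ± 0.41. MHC class I presentation had 14 of 16 genes higher (15 adjusted over the list alone; adjusted p = 1.93e-07). Among them were the peptide transporter Tap1 (1.89 ± 0.35) and the immunoproteasome subunit Psmb9 (2.04 ± 0.39). Of 11 MHC class II genes, 9 rose (9 adjusted over the list alone; adjusted p = 5.87e-05). The protease Ctss was at 3.25 ± 0.64 and the master regulator Ciita at 2.22 ± 0.50. T cell genes rose in 12 of 18 cases (12 adjusted over the list alone; adjusted p = 1.25e-05), led by Cd4 (3.54 ± 0.58), the receptor chain Trac (3.02 ± 0.60) and Cd6 (3.76 ± 0.71). Of 17 apoptosis and cytotoxic effector genes, 11 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 3.89e-05). These included Ifng (4.57 ± 0.83), the chemokine Ccl5 (5.02 ± 1.04) and the pro-apoptotic Pmaip1 (1.69 ± 0.25). Macrophage and monocyte genes rose in 10 of 20 cases (13 higher and 1 lower adjusted over the list alone; adjusted p = 5.87e-05), for example complement C1qb (2.43 ± 0.48). Each of these 6 lists had an adjusted p = 0.416 with an estimated correlation. B cell and plasma cell genes shifted up (7 of 14 higher and 1 lower, 8 and 1 adjusted over the list alone; adjusted p = 0.0366, and adjusted p = 0.645 with an estimated correlation). The antibody light chain Igkc was at 8.69 ± 1.89 and the joining chain Jchain at 7.87 ± 1.80. The mean log2 CPM of the B cell list was -0.51 to 3.28 in allogeneic isotype and -0.63 to -0.20 in syngeneic libraries. Not every allogeneic library was thus raised. Of 10 neutrophil genes, 6 rose and 1 fell (6 and 2 adjusted over the list alone). They included the chemokine receptor Cxcr2 (5.20 ± 0.81), S100a9 (3.89 ± 0.87) and the gelatinase Mmp9 (2.55 ± 0.73), but the list did not pass its test (adjusted p = 0.0676).

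Within the IL-1 family, 14 of 22 ligands and receptors rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 5.69e-05, and adjusted p = 0.416 with an estimated correlation). The epidermal cytokines Il36a, Il36b and Il36g rose by 5.64 ± 0.78 (adjusted p = 0.000114), 3.64 ± 0.53 and 2.97 ± 0.50, and the antagonists Il36rn and Il1rn by 2.35 ± 0.35 and 0.93 ± 0.20. Il1a rose by 1.76 ± 0.35 (adjusted p = 0.00175), the adaptor Myd88 by 1.23 ± 0.15 and Il1rap itself by 0.49 ± 0.17 (adjusted p = 0.0430; 24.3 ± 2.71 against 17.3 ± 2.20 CPM). The call of Il1rap was lost with no filter on low counts (adjusted p = 0.139), with muscle content as a covariate and with the block by description number. It was also lost when any library but allogeneic replicate 3 was left out. Il1b was at 2.08 ± 0.86 (adjusted p = 0.0903) and Il33 at -0.77 ± 0.47 (adjusted p = 0.257). Of 27 NF-kB and IL-1 response genes, 19 rose (20 higher and 1 lower adjusted over the list alone; adjusted p = 7.16e-07, and adjusted p = 0.416 with an estimated correlation). They included the acute-phase genes Saa3 (7.95 ± 1.39) and Saa1 (5.29 ± 0.66), which are similar in sequence, the monocyte attractant Ccl7 (3.35 ± 0.47), Tnf (2.60 ± 0.46) and Il6 (2.67 ± 0.87, adjusted p = 0.0328), while the neutrophil attractant Cxcl1 was at 1.57 ± 0.56 (adjusted p = 0.0513). Il6 lost its call in the same 3 fits, with the replicate block, and without syngeneic replicates 2, 3 or 4 or allogeneic replicates 1 or 2. Type 2 and type 17 cytokine genes moved both ways, 3 of 16 higher and 2 lower (3 and 3 adjusted over the list alone; adjusted p = 0.688). Ccl17 was at 5.38 ± 1.03 and Ccl24 at -2.45 ± 0.51. Immediate early and heat shock genes shifted up (7 of 20 higher, 11 adjusted over the list alone; adjusted p = 0.000804, and adjusted p = 0.416 with an estimated correlation). Junb was at 1.53 ± 0.24. The immediate early list was set to follow tissue handling and RNA quality, and a handling difference was not tested.

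In the epidermis, 9 of 13 activated keratinocyte genes rose (10 adjusted over the list alone; adjusted p = 7.16e-07). Krt16 rose by 6.88 ± 0.79 (adjusted p = 2.62e-05), Krt6b by 8.17 ± 1.09 and Krt6a by 3.81 ± 0.49, the last pair being near-identical in sequence, and the growth factor Ereg by 2.93 ± 0.35. Differentiated keratinocyte genes rose in 13 of 20 cases (13 adjusted over the list alone; adjusted p = 5.69e-05). Among them were the barrier proteins Flg (4.72 ± 0.66) and Hrnr (3.64 ± 0.57) and the desmosomal Dsc1 (1.82 ± 0.25). Both lists had an adjusted p = 0.416 with an estimated correlation. Basal keratinocyte genes split, with Krt14 at 1.5 ± 0.38 and Krt15, a keratin of follicle stem cells, at -3.13 ± 0.58, as the called genes of 9 (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.905). Of 17 sebaceous gland and skin lipid genes, 7 fell and none rose (8 lower adjusted over the list alone; adjusted p = 1.25e-05, and adjusted p = 0.416 with an estimated correlation). The desaturase Scd3 was at -5.71 ± 0.64 (adjusted p = 2.48e-05), the wax synthase Awat2 at -4.62 ± 0.62, Mc5r at -2.04 ± 0.41 and the fatty acid hydroxylase Fa2h at -3.44 ± 0.82. No gene of the 21 hair follicle genes passed (adjusted p = 0.638), and 2 of 8 melanocyte genes rose (2 adjusted over the list alone; adjusted p = 0.544).

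The fibroblast and matrix lists shifted down, though most of their genes did not pass. Among 15 fibroblast genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0003, and adjusted p = 0.416 with an estimated correlation). The matrix protein Dpt (-2.38 ± 0.45), Pi16 (-2.59 ± 0.54) and the surface peptidase Dpp4 (-1.40 ± 0.25) were lower and the interferon-responsive Ly6a higher (1.82 ± 0.33). Of 38 collagen and extracellular matrix genes, 7 fell and 4 rose (8 and 5 adjusted over the list alone; adjusted p = 0.0262 downward, and adjusted p = 0.680 with an estimated correlation). Fap was at -2.09 ± 0.30, Col14a1 at -2.17 ± 0.44 and decorin (Dcn) at -1.79 ± 0.42, against tenascin C (Tnc), a matrix protein of wounds, at 4.00 ± 0.50 (adjusted p = 5.93e-05). The fibrillar collagens did not pass: Col1a1 was at -0.94 ± 0.57, Col1a2 at -1.02 ± 0.49 and Col3a1 at -1.10 ± 0.49. Fn1 (-0.21 ± 0.61), Acta2 (-0.06 ± 0.32), Pdgfra (-1.10 ± 0.45) and Pdgfrb (-0.28 ± 0.28) did not pass either. Among 27 TGF-beta response genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone; adjusted p = 0.904), with Skil (1.45 ± 0.16), Thbs1 (2.19 ± 0.31) and Ccn1 (1.48 ± 0.29) higher and Ltbp3 (-1.11 ± 0.20) lower. Receptors inhibited by nintedanib and their ligands had 1 of 25 genes higher and 4 lower (2 and 5 adjusted over the list alone, with a list adjusted p = 0.155). That list also holds the kinases Lck, Lyn and Src, which are neither receptors nor ligands. Schwann cell and nerve genes fell in 5 of 10 cases (5 adjusted over the list alone; adjusted p = 0.0144, and adjusted p = 0.435 with an estimated correlation). They included the myelin genes Mbp (-1.48 ± 0.32) and Pmp22 (-1.03 ± 0.27). Adipocyte genes shifted down (2 of 17 lower, 1 adjusted over the list alone; adjusted p = 0.0210, and adjusted p = 0.669 with an estimated correlation), with the hormone leptin (Lep) at -4.56 ± 1.23 and Car3 at -1.71 ± 0.60. The call of Car3 was lost without any library but syngeneic replicate 3, with no filter, with either block and with muscle content as a covariate.

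Of the remaining lists, gamma-delta T cell genes had 1 of 7 higher (Trgc2, 4.22 ± 0.80) and 2 lower (Trdc, -2.73 ± 0.77, and Trdv4, -3.55 ± 0.89), with 1 and 3 adjusted over the list alone (adjusted p = 0.129). Dendritic and Langerhans cell genes had 3 of 12 higher and 2 lower (3 and 3 adjusted over the list alone; adjusted p = 0.905). Ly75 was at 2.23 ± 0.37, Cd209a at -3.35 ± 0.69 and Siglech, a plasmacytoid dendritic cell receptor, at -5.27 ± 1.09. The median of that list was 0.01 and its mean -0.26. Mast cell genes rose in 3 of 11 cases (3 adjusted over the list alone; adjusted p = 0.507), endothelial genes fell in 2 of 16 (1 adjusted over the list alone; adjusted p = 0.165), and none of 11 pericyte genes (adjusted p = 0.212) or 6 red blood cell genes (adjusted p = 0.795) passed. Cell cycle genes shifted up with 2 of 26 called (0 adjusted over the list alone; adjusted p = 0.00181, and adjusted p = 0.645 with an estimated correlation). Skeletal muscle genes, which mark muscle caught in the skin sample, took 6.06 ± 1.10% of counts in syngeneic and 2.52 ± 2.67% in allogeneic isotype libraries and only 0.00394% in allogeneic replicate 1. They shifted down with 2 of 20 lower (0 adjusted over the list alone; adjusted p = 0.000504, and adjusted p = 0.624 with an estimated correlation). Among them were Pvalb (-3.89 ± 1.2). The mitochondrially encoded genes, abundant in muscle, also shifted down, with 0 of 13 called and 8 lower adjusted over the list alone (adjusted p = 9.75e-06, and adjusted p = 0.416 with an estimated correlation). No list kept its call with an estimated correlation in this comparison. Pvalb lost its call in 4 and Trdc in 2 of 19 other settings.

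Treatment with the anti-IL1RAP antibody was compared with isotype antibody in allogeneic recipients to see how blocking this co-receptor changes diseased skin. Of the activated keratinocyte genes 10 of 13 fell, as did 10 of 20 differentiated keratinocyte genes, Il36a, Il36b and Il36g and some interferon-stimulated and neutrophil genes. Some sebaceous gland, fibroblast, matrix and myelin genes rose. Krt16 went from 2386 ± 1118 to 51.4 ± 21.0 CPM and Il36a from 30.9 ± 16.4 to 1.67 ± 0.986 CPM, while Scd3 went from 2.46 ± 1.65 to 144 ± 52.7 CPM (SD, n = 4 in each group). In all, 2204 genes changed, 1142 higher and 1062 lower with the antibody, and 17 of 33 lists shifted, 8 up and 9 down, none of them with an estimated correlation (lowest adjusted p = 0.245). Without allogeneic isotype replicate 4, anti-IL1RAP replicate 3 or anti-IL1RAP replicate 4 the count was 1320, 1353 and 1284. The largest increases were of Serpinb6e (6.5 ± 0.83, adjusted p = 0.000221), Sphkap (6.13 ± 1.03), Nnat (6.06 ± 1.49), Scd3 (5.86 ± 0.65, adjusted p = 9.71e-05), Rxfp1 (5.83 ± 1.29) and Aadacl4 (5.58 ± 0.98). The largest decreases were of Chil4 (at least 768-fold lower), Akr1d1 (-8.29 ± 1.73) and 4 cystatin-type inhibitors with near-identical relatives, Stfa2 (-8.86 ± 1.32), Csta3 (-8.22 ± 1.61), Cstdc5 (-8.10 ± 1.54) and Stfa1 (-8.01 ± 1.23), with adjusted p up to 0.0196.

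**Figure D1:**
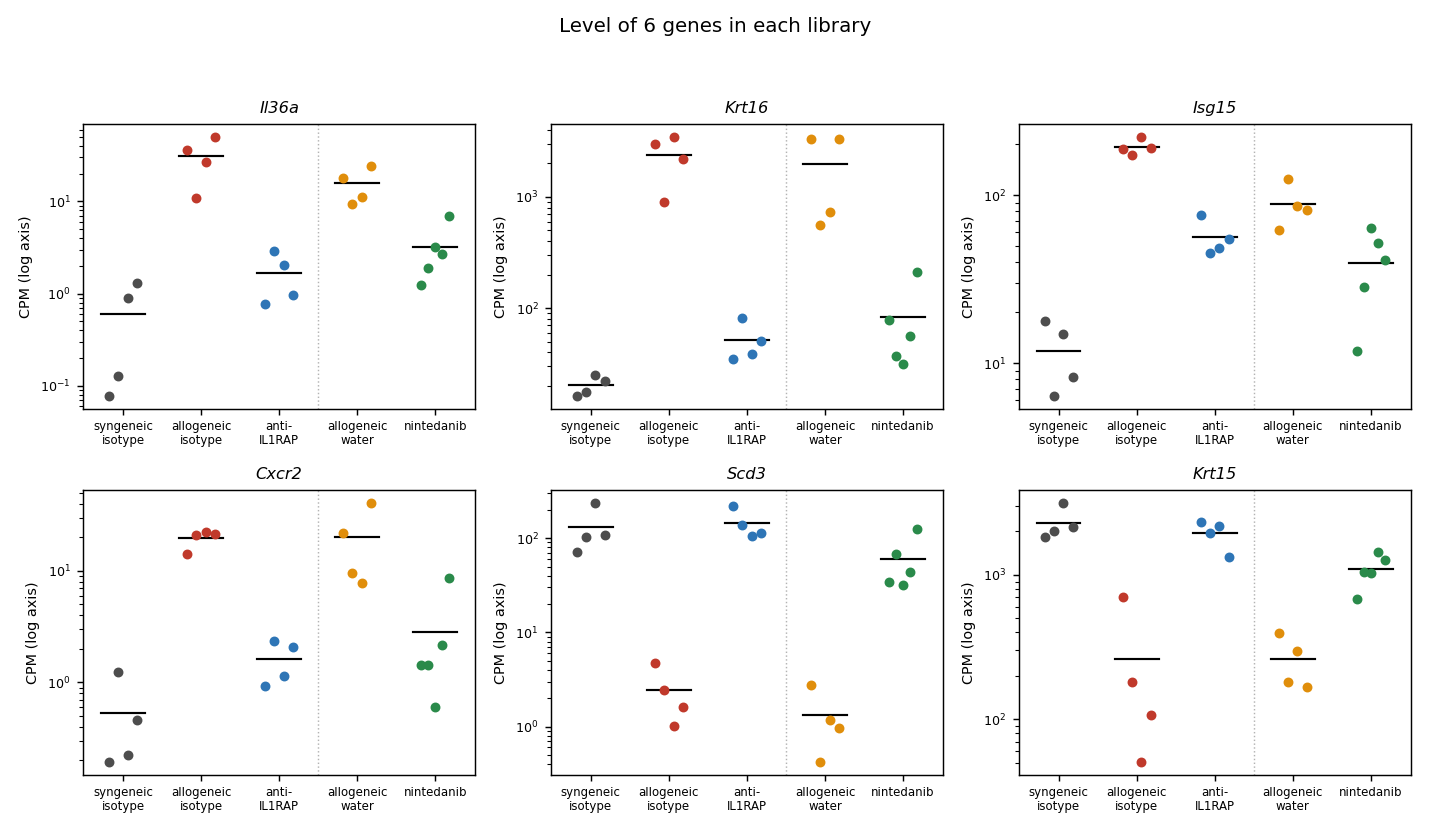
Level of 6 genes in each library, in CPM on a log axis, for the 5 groups on the horizontal axis; each point is 1 library, the black line is the group mean, and the dotted line parts the 2 counting runs. Scd3 averaged 2.46 CPM in allogeneic isotype, 144 with anti-IL1RAP, 1.33 in allogeneic water and 60.4 with nintedanib.

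Activated keratinocyte genes fell in 10 of 13 cases (10 adjusted over the list alone; adjusted p = 2.20e-09, and adjusted p = 0.245 with an estimated correlation). Krt6b was at -7.12 ± 1.04, Krt16 at -5.54 ± 0.74 and Ereg at -2.67 ± 0.34. Of 20 differentiated keratinocyte genes, 10 fell (13 adjusted over the list alone; adjusted p = 7.00e-07). They included Flg (-4.63 ± 0.66), Hrnr (-2.96 ± 0.56) and Dsc1 (-1.42 ± 0.25). Among IL-1 family genes 11 of 22 fell and none rose (14 and 2 adjusted over the list alone; adjusted p = 3.96e-05): Il36a (-4.20 ± 0.72, adjusted p = 0.00157), Il36b (-3.13 ± 0.51), Il36g (-2.27 ± 0.49), Il36rn (-2.28 ± 0.35), Il1a (-1.46 ± 0.35), Il1rn (-0.82 ± 0.20) and the IL-36 receptor Il1rl2 (-0.68 ± 0.14) were among them. These last 2 lists had an adjusted p = 0.397 with an estimated correlation. Il1rap, whose product the antibody binds, was at -0.41 ± 0.17 (adjusted p = 0.140; 18.3 ± 3.02 against 24.3 ± 2.71 CPM), Il1b at -1.02 ± 0.83 (adjusted p = 0.501) and Il33 at 0.36 ± 0.46 (adjusted p = 0.704). NF-kB and IL-1 response genes fell in 5 of 27 cases (6 adjusted over the list alone; adjusted p = 0.00358, and adjusted p = 0.698 with an estimated correlation). Among them were Saa3 (-5.41 ± 1.2), Saa1 (-2.74 ± 0.54) and the collagenase Mmp13 (-5.51 ± 1.36), while Il6 (-1.27 ± 0.79) and Cxcl1 (-0.14 ± 0.54) did not pass. Of 10 neutrophil genes, 4 fell (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.0579), namely Cxcr2 (-3.58 ± 0.73), Mmp9 (-2.83 ± 0.74), S100a9 (-2.96 ± 0.83) and S100a8 (-2.78 ± 0.84).

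Of the 33 interferon-stimulated genes 6 fell (11 adjusted over the list alone; adjusted p = 6.34e-08, and adjusted p = 0.698 with an estimated correlation). Cxcl11 was at -3.19 ± 0.68, Isg15 at -1.78 ± 0.39, Oas2 at -1.57 ± 0.40 and the antiviral Mx1 at -1.63 ± 0.44. MHC class I genes shifted down with 0 of 16 called (adjusted p = 0.0176, and adjusted p = 0.735 with an estimated correlation), H2-T22 being at -0.76 ± 0.32, and MHC class II genes did not shift (0 of 11 called; adjusted p = 0.337). Ctss was at -1.41 ± 0.60. T cell genes shifted down with 0 of 18 called (adjusted p = 0.0221, and adjusted p = 0.735 with an estimated correlation), Cd5 being at -1.03 ± 0.45 and Cd6 at -1.19 ± 0.63. Cytotoxic genes shifted down with 1 of 17 lower, Pmaip1 (-1.23 ± 0.25), and 1 higher (1 and 1 adjusted over the list alone; adjusted p = 0.0292, and adjusted p = 0.735 with an estimated correlation), while Ifng (-1.43 ± 0.68) and Ccl5 (-2.19 ± 0.90) did not pass. Cell cycle genes shifted down with 0 of 26 called (adjusted p = 0.0254, and adjusted p = 0.801 with an estimated correlation). Macrophage genes did not shift as a list (1 of 20 lower; adjusted p = 0.119), and in the B cell and plasma cell list the antibody gene Iglc2 fell (-4.58 ± 1.28, 1 of 14; adjusted p = 0.267). Iglc2 lost its call in 8 of 19 other settings, among them both allogeneic controls, only the groups compared and both replicate blocks. Dendritic and Langerhans cell genes Cd207, the Langerhans cell lectin, and Cd209a rose by 2.52 ± 0.62 and 3.57 ± 0.69 (2 of 12, 3 adjusted over the list alone; adjusted p = 0.160). Cd207, also in the gamma-delta T cell list, was its 1 called gene of 7 (adjusted p = 0.0929).

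Sebaceous gland genes rose in 7 of 17 cases (9 adjusted over the list alone; adjusted p = 2.55e-08, and adjusted p = 0.245 with an estimated correlation). Scd3 was at 5.86 ± 0.65, Awat2 at 4.97 ± 0.63, Far2 at 2.79 ± 0.57 and Mc5r at 2.28 ± 0.41. Of 15 fibroblast genes 5 rose (9 adjusted over the list alone; adjusted p = 5.47e-05). Among them were Dpt (1.93 ± 0.44), Pi16 (2.12 ± 0.53), Dcn (1.88 ± 0.42) and Dpp4 (0.98 ± 0.25), and 5 of 10 Schwann cell genes rose (6 adjusted over the list alone; adjusted p = 7.33e-05). They included Mbp (1.62 ± 0.33), Pmp22 (1.31 ± 0.27) and Prx (1.60 ± 0.35). Both had an adjusted p = 0.397 with an estimated correlation. Collagen and matrix genes shifted up, 6 of 38 higher and 1 lower (9 and 2 adjusted over the list alone; adjusted p = 0.00274, and adjusted p = 0.735 with an estimated correlation). Fap was at 1.47 ± 0.30 and Col14a1 at 2.00 ± 0.44, and Tnc fell by 2.87 ± 0.48. The fibrillar collagens were at 1.43 ± 0.57 (Col1a1, adjusted p = 0.121), 1.49 ± 0.49 (Col1a2, adjusted p = 0.0613) and 1.29 ± 0.49 (Col3a1, adjusted p = 0.105), and Fn1 (0.24 ± 0.61), Acta2 (0.38 ± 0.32), Pdgfra (0.96 ± 0.45) and Pdgfrb (0.35 ± 0.28) did not pass either. TGF-beta response genes Skil (-1.12 ± 0.16), Thbs1 (-1.47 ± 0.31) and the receptor Tgfbr1 (-0.43 ± 0.13) fell and Ltbp3 (0.84 ± 0.20) rose (1 of 27 higher and 3 lower, 2 and 3 adjusted over the list alone; adjusted p = 0.811). Of 25 nintedanib target receptors and ligands the fibroblast growth factors Fgf18 (3.12 ± 0.81) and Fgf7 (1.02 ± 0.31) rose (2 adjusted over the list alone; adjusted p = 0.0338, and adjusted p = 0.698 with an estimated correlation). Fgf7 lost its call in 11 of 19 other settings, among them the fit of only the groups compared, no filter and both replicate blocks. Krt15 rose by 2.90 ± 0.57 and Krt14 fell by 1.28 ± 0.37 (basal keratinocyte list, 1 and 1 of 9; adjusted p = 0.928).

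The other lists held few called genes. Adipocyte genes shifted up with Lep (3.83 ± 1.2) as the 1 called gene of 17 (0 adjusted over the list alone; adjusted p = 0.00575). The call of Lep was lost in 13 of 19 other settings, including the removal of any single library. Mast cell genes (0 of 11 called; adjusted p = 0.0125) and endothelial genes (0 of 16; adjusted p = 0.0285) shifted up as lists. Each of these 3 lists had an adjusted p = 0.735 with an estimated correlation. Type 2 and type 17 cytokine genes had 1 of 16 higher (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.889), pericyte genes 1 of 11 higher (adjusted p = 0.208), and immediate early genes 1 of 20 higher and 1 lower, Junb (-0.83 ± 0.24), with 0 adjusted over the list alone (adjusted p = 0.249). No gene passed in the hair follicle (adjusted p = 0.325), melanocyte (adjusted p = 0.889), red blood cell (adjusted p = 0.889) or mitochondrially encoded lists (adjusted p = 0.178). Skeletal muscle genes, at 2.11 ± 1.37% of counts with the antibody and 2.52 ± 2.67% with isotype, had none called (adjusted p = 0.133), with an upward test and a median of -0.55. No list kept its call with an estimated correlation. Of 19 other settings, calls were also lost in 9 for S100a8, 7 for Junb and Tgfbr1, 6 for Krt14 and S100a9, 5 for Mx1, 3 for Dpp4, Fgf18 and Mmp9, 2 for Chil4 and Pi16 and 1 for Dcn, Il1a, Ltbp3 and Oas2.

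**Figure D2:**
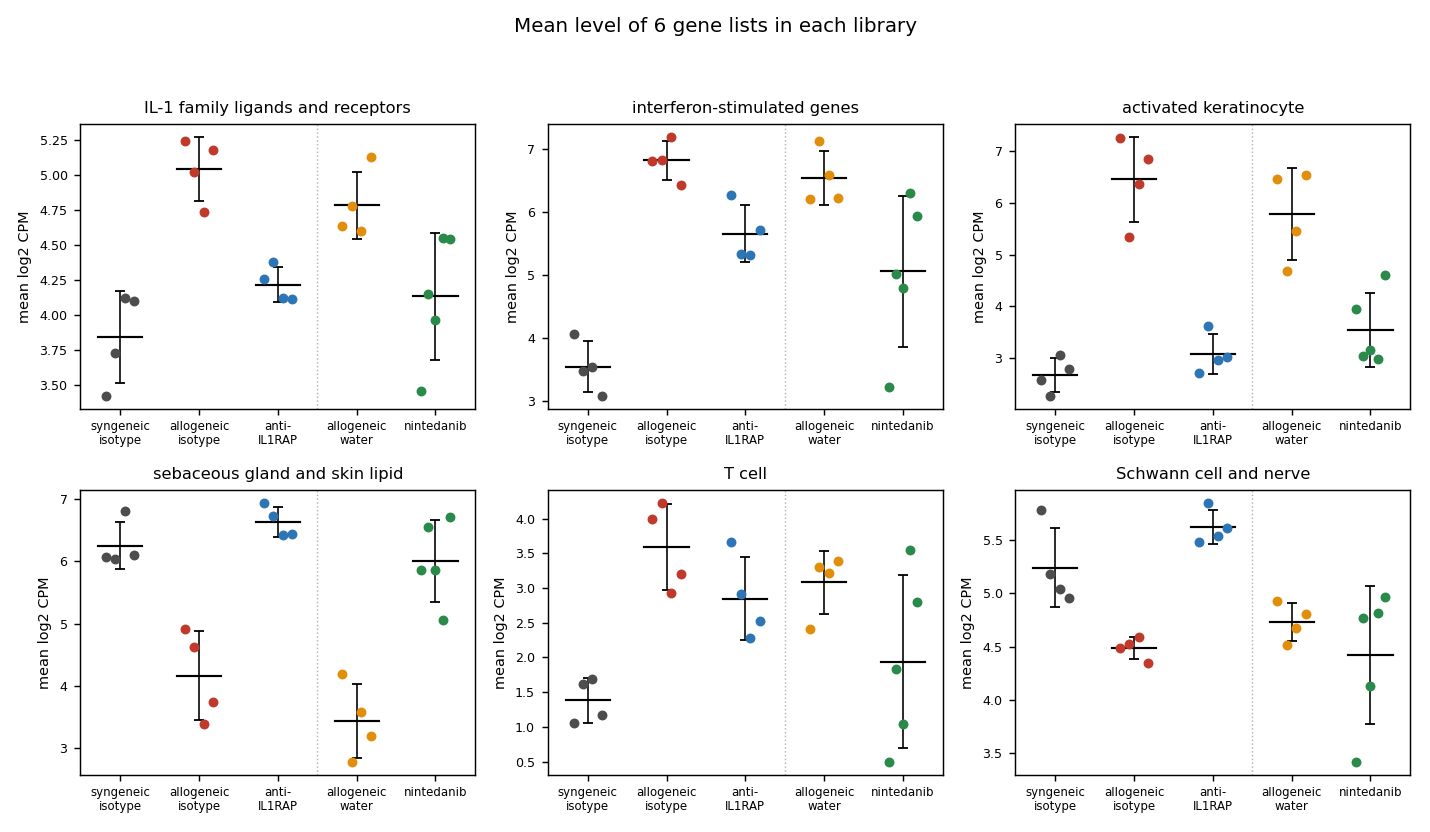
Mean log2 CPM of 6 gene lists in each library for the 5 groups on the horizontal axis; points are libraries, bars are mean ± SD, and the dotted line parts the 2 counting runs. The activated keratinocyte list averaged 6.45 in allogeneic isotype and 3.08 with anti-IL1RAP, and 5.78 in allogeneic water and 3.55 with nintedanib.

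Nintedanib, an antifibrotic drug, was compared with water in allogeneic recipients. Of the activated keratinocyte genes 6 of 12 fell, and of the sebaceous gland genes 9 of 17 rose. Among interferon-stimulated genes 6 of 33 fell, among immediate early genes 6 of 20, neutrophil genes 3 of 10, MHC class I genes 2 of 16 and macrophage genes 2 of 20, and none of 11 MHC class II genes passed. Krt16 went from 1993 ± 1562 to 82.5 ± 73.1 CPM, and Scd3 from 1.33 ± 0.997 to 60.4 ± 38.7 CPM (SD, n = 4 for water and 5 for nintedanib). With all 21 libraries in the fit 1906 genes changed, 1137 higher and 769 lower with nintedanib, and 18 of 32 lists shifted, 4 up and 14 down, none of them with an estimated correlation (lowest adjusted p = 0.390). When the fit held only these 9 libraries, 94 genes passed. Of 56 named genes that could be tested, 11 remained called, namely AAdacl4fm3, Serpinb6e, Aadacl4, Krt16, Zc3h12a, Krt15, Ereg, Far2, Scd3, Awat2 and Nr4a1. The SEs and adjusted p given for nintedanib are those of the fit with all 21 libraries. They may understate the spread among these 9. The count was 242 among libraries with a note on 2 sequencing lanes and 333 among those without it, and 1067, 1213, 782, 1235 and 1231 without water replicates 2, 3 or 4 or nintedanib replicates 1 or 3. The largest increases were of the esterase-like genes AAdacl4fm3 (8.83 ± 1.37) and Aadacl4 (8.27 ± 1.30), which are related in sequence, Serpinb6e (8.55 ± 1.09, adjusted p = 0.000476), Serpina3j (7.63 ± 1.55), Akr1cl (at least 35.2-fold higher) and Cpn2 (at least 26.3-fold higher). The largest decreases were of the cytokine Il24 (-5.54 ± 0.89), Krt6b (-5.28 ± 0.87), Serpinb3a (-4.65 ± 0.86), Krt16 (-4.60 ± 0.64, adjusted p = 0.000844) and the cornified envelope genes Sprr2a1 (-4.55 ± 1.10) and Sprr1b (-4.11 ± 0.93), with adjusted p up to 0.0163.

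Activated keratinocyte genes fell in 6 of 12 cases (8 adjusted over the list alone; adjusted p = 9.42e-07, and adjusted p = 0.409 with an estimated correlation). They included Ereg (-2.16 ± 0.31) and Krt6a (-2.23 ± 0.42). Of 20 differentiated keratinocyte genes 5 fell (8 adjusted over the list alone; adjusted p = 4.25e-05, and adjusted p = 0.432 with an estimated correlation). Among them were Hrnr (-1.84 ± 0.50), Lce1a1 (-1.41 ± 0.37) and Krt2 (-3.81 ± 1.12). In the basal keratinocyte list Krt15 rose by 2.07 ± 0.54, and Krt14 (-1.36 ± 0.35) and the integrin Itga6 (-0.70 ± 0.17) fell (1 and 2 of 9; adjusted p = 0.0944). Sebaceous gland genes rose in 9 of 17 cases (11 adjusted over the list alone; adjusted p = 6.49e-09, and adjusted p = 0.390 with an estimated correlation). Far2 was at 5.68 ± 0.65, Scd3 at 5.51 ± 0.64 (adjusted p = 0.000419 each), Awat2 at 5.11 ± 0.65 and Mc5r at 2.62 ± 0.40. Hair follicle genes rose in 13 of 22 cases (21 adjusted over the list alone; adjusted p = 0.00395, and adjusted p = 0.671 with an estimated correlation). They included the hair keratins Krt34 (10.77 ± 2.66) and Krt83 (10.09 ± 2.5), whose relatives are similar in sequence. Hair follicle genes took 6.88% of counts in nintedanib replicate 1 and 2.65% in replicate 3, and at most 0.0690% in any other library. Melanocyte genes shifted up with 1 of 8 called, Mitf (1.18 ± 0.29), and 5 adjusted over the list alone (adjusted p = 0.0102, and adjusted p = 0.491 with an estimated correlation). That list was at a mean log2 CPM of 3.78 and 3.50 in replicates 1 and 3, and 0.70, 1.30 and 2.10 in the other nintedanib libraries, against 1.16 ± 0.75 in water.

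With nintedanib replicates 1 and 3 left out, a setting chosen after the data were seen, 1225 genes passed, of which 772 were among the 1906. Of 58 named genes that could be tested, 29 lost their call: Il36a, Sprr2a1, Il36rn, Saa1, Ptgs2, Cxcl2, Socs1, Oas3, Tap2, Nlrc5, Fap, Tnc, Thbs1, Ccn1, Skil, C1qa, Cxcr2, Mmp9, Ltf, Ly75, Cd209a, Dpp4, Ly6a, Itga6, Krt14, Hrnr, Lce1a1, Krt2 and Mitf. In this comparison (nintedanib against allogeneic water) 16 lists shifted without those libraries. The T cell (adjusted p = 0.230), neutrophil (adjusted p = 0.346), cytotoxic (adjusted p = 0.0991), type 2 and type 17 (adjusted p = 0.507), hair follicle (adjusted p = 0.0688), melanocyte (adjusted p = 0.404) and endothelial lists (adjusted p = 0.612) no longer did. The endothelial list then tested upward, with a mean log2 CPM of 3.10 and 3.73 in replicates 1 and 3 and 5.22, 4.32 and 4.55 in the others, against 4.59 ± 0.19 in water. The collagen and matrix list, with 0 of 38 called, tested upward at an adjusted p = 0.00498, without a test at an estimated correlation. Over all 25 other settings, the calls lost most often were those of Ly6a (18), Krt2 and Ltf (16 each), Alas2 (15), Skil (14), C1qa, Dpp4 and Oas3 (13 each), Cd209a and Socs1 (12 each), Ptgs2 (11), Cxcl2 (11 of 22 in which it was tested), and Fap and Tnc (10 each). Awat2, Ereg, Far2, Krt16, Scd3 and Serpinb6e never lost theirs, and the other named genes lost theirs in 1 to 9.

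**Figure D3:**
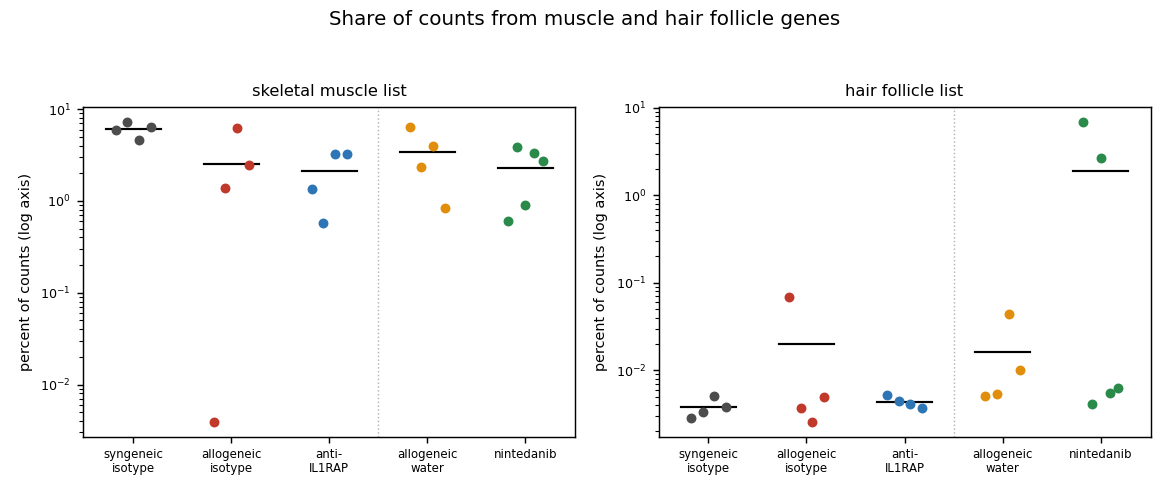
Percent of counts from the skeletal muscle list (left) and the hair follicle list (right) in each library, on log axes, for the 5 groups on the horizontal axis; points are libraries, black lines are group means, and the dotted line parts the 2 counting runs. Nintedanib replicates 1 and 3 had hair follicle shares of 6.88% and 2.65%, and allogeneic isotype replicate 1 a muscle share of 0.00394%.

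Among immune genes, 6 of 33 interferon-stimulated genes fell with nintedanib (10 adjusted over the list alone; adjusted p = 6.92e-13). Oas2 was at -1.87 ± 0.37, Stat2 at -1.32 ± 0.27, Oas3 at -1.63 ± 0.48 and the signalling inhibitor Socs1 at -1.41 ± 0.41. MHC class I genes Tap2 (-1.04 ± 0.29) and Nlrc5 (-0.88 ± 0.25) fell (2 of 16, 12 adjusted over the list alone; adjusted p = 1.82e-07), and MHC class II genes shifted down with 0 of 11 called (adjusted p = 3.22e-05). The mean log2 CPM of the class I list was 5.64 to 7.98 in nintedanib and 7.74 to 8.32 in water libraries. That of the class II list was 4.16 to 7.12 and 6.31 to 7.46, so both ranges overlapped. The calls of Oas3, Socs1, Tap2 and Nlrc5 were lost without replicates 1 and 3. Interferon-stimulated genes were at a mean log2 CPM of 3.22, 5.02, 4.79, 6.31 and 5.94 in nintedanib replicates 1 to 5, where water libraries ranged from 6.21 to 7.13, so 4 of 5 lay below all of them. Macrophage genes fell in 2 of 20 cases, C1qa (-1.48 ± 0.42) among them, with 6 adjusted over the list alone (adjusted p = 3.76e-06). The macrophage list also overlapped, at 3.97 to 5.98 in nintedanib and 5.52 to 6.30 in water libraries. Of 10 neutrophil genes Cxcr2 (-2.82 ± 0.65), Mmp9 (-2.47 ± 0.67) and the granule protein Ltf (-6.95 ± 2.03) fell (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.0125), and these calls and that of C1qa were also lost without replicates 1 and 3. In the cytotoxic list Pmaip1 fell (-1.02 ± 0.23, 1 of 17; adjusted p = 0.000556). The IL-1 family had 6 of 22 genes lower and 1 higher (9 and 2 adjusted over the list alone; adjusted p = 7.73e-05). These 7 lists had an adjusted p = 0.432 with an estimated correlation. Il36a fell by 2.31 ± 0.61 (adjusted p = 0.0253), Myd88 by 0.91 ± 0.14 (adjusted p = 0.00153), Il36rn by 1.28 ± 0.32 and Il1rl2 by 0.56 ± 0.13, while Il1b (-2.51 ± 0.80, adjusted p = 0.0557), Il36g (-1.26 ± 0.44, adjusted p = 0.0764), Il1a (-0.45 ± 0.33), Il33 (-0.40 ± 0.44), Il1rn (-0.31 ± 0.19) and Il1rap (-0.19 ± 0.16) did not pass. NF-kB and IL-1 response genes fell in 5 of 27 cases (17 lower and 1 higher adjusted over the list alone; adjusted p = 3.14e-07, and adjusted p = 0.409 with an estimated correlation). Among them were the RNase Zc3h12a (-1.26 ± 0.20), the prostaglandin synthase Ptgs2 (-1.88 ± 0.51), Cxcl2 (-4.88 ± 1.40) and Saa1 (-2.16 ± 0.57), and Il6 (-1.61 ± 0.76) and Cxcl1 (-0.95 ± 0.53) did not pass.

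T cell genes shifted down with 0 of 18 called (adjusted p = 9.25e-05), Cd4 being at -1.36 ± 0.49 and the list at 0.50, 1.83, 1.04, 3.54 and 2.79 log2 CPM in nintedanib replicates 1 to 5 (2.41 to 3.39 in water). In the type 2 and type 17 list the receptor Il4ra fell by 1.34 ± 0.25 (1 of 16, 3 adjusted over the list alone; adjusted p = 0.0291). Both had an adjusted p = 0.491 with an estimated correlation. Immediate early and heat shock genes fell in 6 of 20 cases (13 lower and 1 higher adjusted over the list alone; adjusted p = 2.74e-05, and adjusted p = 0.409 with an estimated correlation). They included Nr4a1 (-2.14 ± 0.39), Dusp1 (-1.60 ± 0.34), Hspa1a (-0.98 ± 0.20) and Dnajb1 (-0.87 ± 0.18). The list was set to follow tissue handling and RNA quality. Its mean log2 CPM was 5.89 to 6.26 in nintedanib and 6.68 to 7.02 in water libraries, and a handling difference was not tested. Fibroblast genes shifted up, Dpp4 (0.82 ± 0.23) higher and Ly6a (-0.999 ± 0.31) lower of 15 (2 and 1 adjusted over the list alone; adjusted p = 0.0440), and endothelial genes shifted down with 0 of 16 called (adjusted p = 0.0244), each with an adjusted p = 0.671 with an estimated correlation. The endothelial direction turned without replicates 1 and 3. Collagen and matrix genes did not shift (adjusted p = 0.250), with Fap (1.09 ± 0.28) higher and Tnc (-1.48 ± 0.42) lower of 38 (1 and 1 adjusted over the list alone). Col1a1 (1.25 ± 0.55), Col1a2 (1.19 ± 0.47), Col3a1 (0.77 ± 0.47), Fn1 (0.24 ± 0.58), Acta2 (0.14 ± 0.30), Pdgfra (0.46 ± 0.43) and Pdgfrb (0.09 ± 0.26) did not pass. TGF-beta response genes Thbs1 (-1.13 ± 0.28), Ccn1 (-1.04 ± 0.27) and Skil (-0.51 ± 0.15) fell (3 of 27, 3 lower and 1 higher adjusted over the list alone; adjusted p = 0.220). None of the 25 nintedanib target receptors and ligands passed (adjusted p = 0.231), the lowest p being that of Pgf (-0.97 ± 0.30, adjusted p = 0.0503). Dendritic cell genes Ly75 (-1.51 ± 0.33) and Cd209a (2.28 ± 0.65) changed in opposite directions (adjusted p = 0.168), and Slc4a1 (4.02 ± 1.12) and Alas2 (2.62 ± 0.80) rose among 6 red blood cell genes (6 adjusted over the list alone; adjusted p = 0.0989), genes whose share of counts was 0.250% in nintedanib replicate 4 and at most 0.0491% elsewhere. B cell and plasma cell genes had 1 of 14 higher (adjusted p = 0.549) and mast cell genes 1 of 11 lower (adjusted p = 0.229). No gene passed in the cell cycle (adjusted p = 0.132), gamma-delta T cell (adjusted p = 0.999), adipocyte (adjusted p = 0.0608), skeletal muscle (adjusted p = 0.289), pericyte (adjusted p = 0.690) or Schwann cell (adjusted p = 0.246) lists.

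Genes changed by treatment were then set against genes changed in disease. Of the 4621 genes called between allogeneic and syngeneic isotype skin, 1884 (40.8%) changed in the opposite direction with anti-IL1RAP, where independent lists would share 247, and 1 changed in the same direction, where 251 would. These comparisons share the isotype libraries. In simulations of 19438 genes with no effect, the sharing alone gave a correlation of fold changes of -0.514. A fit of the first counting run gave -0.806. The covariance was -0.0771 in the simulations and -0.844 in that fit. Opposite calls averaged 0.05, against 3108, but hardly any gene is called where no effect is simulated. That count is therefore no measure of what the sharing adds. With the isotype libraries split between the comparisons, over 6 splits, 1655 genes on average (range 1341 to 1970) changed in opposite directions and 35.7 (range 0 to 172) in the same direction. Nintedanib, which shares no library with the disease comparison, changed 851 of the 4621 genes in the opposite direction (18.4%; 206 for independent lists), 353 from lower to higher and 498 from higher to lower, and 11 in the same direction (224 for independent lists). Both treatments changed 640 genes in the same direction (103 for independent lists), 303 higher and 337 lower, and 2 in opposite directions (102 for independent lists). These overlaps hold for the 1906 nintedanib calls of the fit with all 21 libraries. The 94 calls with only the 9 libraries and the 782 without water replicate 4 are fewer than 851. An overlap of that size cannot arise there. Across 17132 genes with counts in both runs, which are not independent replicates, the nintedanib effect had a correlation of -0.549 with the disease effect (exact permutation p = 0.0556 over all regroupings of the 9 libraries) and of 0.582 with the anti-IL1RAP effect (exact permutation p = 0.0476). Over all 20462 genes tested, the fold changes of the fit had correlations of -0.320 and 0.345.

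A disease score over 200 higher and 200 lower genes was lower in nintedanib (-0.502 ± 0.452) than in water libraries (1.69 ± 0.338), a difference of -2.19 on the log2 scale. The exact two-sided permutation p = 0.00794 is the smallest that regrouping these libraries can give, and within libraries alike in the sequencing lane note it was 0.0167. Syngeneic libraries, of the other counting run, were at -1.92 ± 0.0879. Allogeneic isotype libraries of that run, on which the genes were also chosen, ranged from 3.34 to 3.74. Levels therefore cannot be compared across runs. Of the genes in the nintedanib score, 36 had counts in 1 counting run only. For anti-IL1RAP the score was -7.52 ± 0.0479 against -7.37 ± 0.0103 for isotype and -7.65 ± 0.0977 for syngeneic libraries, a difference of -0.152 (exact two-sided permutation p = 0.0286, the smallest that 70 regroupings can give). The size depends on the genes used, at -0.0902 with fewer genes per direction (50), -0.433 with more and no fold threshold, and -0.862 with only symbols of both runs, the last chosen after the data were seen (exact permutation p = 0.0286 each). Of the genes in this score, 265 had counts in 1 counting run only, since they were chosen between water and syngeneic libraries. With genes chosen on 2 isotype libraries and scored on the other 2, the difference averaged -3.13 (SD 0.234 over 6 choices, range -3.40 to -2.79), with isotype at 3.23, anti-IL1RAP at 0.101 and syngeneic at -1.51.

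The anti-IL1RAP and nintedanib effects were compared gene by gene, each relative to the control of its counting run. No gene passed edgeR's test of the difference at the adjusted threshold, while 2495 of 20462 genes had an unadjusted p under 0.05 and DESeq2 called 364. Of the 20462 genes, 19677 had counts in isotype or anti-IL1RAP libraries and 17917 in water or nintedanib libraries. Where 1 side has no counts, the difference is only the effect of the other treatment. The 0 depends on single libraries, with 2, 7 and 2 genes without nintedanib replicates 1, 2 or 4, 4 without replicates 1 and 3 and 687 without replicates 2 and 4, pairs chosen after the data were seen. The lowest adjusted p was 0.104. The genes of lowest p were Pkn3 (1.12 ± 0.19), the chemokine-binding Ackr1 of venules (1.54 ± 0.29) and Zfyve21 (0.74 ± 0.14), more positive for anti-IL1RAP, and Gm17232 (-5.94 ± 1.00), Hddc2 (-1.17 ± 0.21) and 2310002F09Rik (-3.26 ± 0.59), more negative. Il36a differed by -1.89 ± 0.89 (adjusted p = 0.404), Il1a by -1.02 ± 0.48 (adjusted p = 0.398), Il36g by -1.01 ± 0.64, Il1rn by -0.51 ± 0.28, Il1rap by -0.21 ± 0.23, Il1b by 1.49 ± 1.14, Il33 by 0.76 ± 0.64, Il6 by 0.34 ± 1.09 and Cxcl1 by 0.80 ± 0.75, with adjusted p of 0.398 or more. Among matrix genes Col1a1 differed by 0.18 ± 0.77, Col1a2 by 0.29 ± 0.67, Col3a1 by 0.52 ± 0.67, Acta2 by 0.24 ± 0.44, Pdgfra by 0.50 ± 0.62 and Pdgfrb by 0.26 ± 0.38. Fn1 did not pass either, and its direction turned in several other settings. As lists, 17 of 33 shifted, 13 more positive for anti-IL1RAP and 4 more negative, none of them with an estimated correlation (lowest adjusted p = 0.666). The 33 include the mitochondrially encoded list, which has no counts in water and nintedanib libraries. Fry called the Schwann cell list alone (adjusted p = 0.0371), whose mean log2 CPM was 5.62 ± 0.16 with anti-IL1RAP and 4.49 ± 0.11 with isotype, and 4.42 ± 0.65 with nintedanib and 4.73 ± 0.18 with water.

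Water-treated allogeneic recipients were also compared across counting runs, where counting run and group cannot be told apart. Against syngeneic isotype, 4651 genes were higher and 6427 lower, a total of 11078, around a median log2 fold change of -0.13 over all genes. The largest were the same mitochondrial genes under different names, COX1, CYTB, ND1, ND2, ND4 and ND5 at 0 counts in syngeneic libraries and mt-Co1, mt-Cytb, mt-Nd1, mt-Nd2 and mt-Nd4 at 0 in water libraries, along with the ribosomal Rn18s-rs5. All 13 mitochondrially encoded genes of that list, which holds the mt- names, were at 0 in water libraries. Among the 16 genes named in every comparison, Il36a (4.68 ± 0.75), Il36g (2.71 ± 0.49), Il1b (2.81 ± 0.88, adjusted p = 0.0113), Il6 (2.79 ± 0.87), Il1a (0.88 ± 0.35), Il1rn (0.87 ± 0.20) and Il1rap (0.58 ± 0.17) were higher, while Il33 (0.31 ± 0.46), Cxcl1 (1.16 ± 0.56), Col1a1 (-0.49 ± 0.56), Col1a2 (-0.85 ± 0.49), Col3a1 (-0.75 ± 0.49), Fn1 (0.51 ± 0.61), Acta2 (-0.05 ± 0.32), Pdgfra (-1.02 ± 0.45) and Pdgfrb (-0.38 ± 0.28) did not pass. Il1a lost its call in 7 of 18 other settings, among them the term for the lane note and muscle content as a covariate. Il1b lost its call in 3, both replicate blocks and without water replicate 4, Il6 without water replicate 3, and COX1, CYTB, ND1, ND2, ND4 and ND5 with both allogeneic controls. Lists shifted in 14 of 33 cases, none of them with an estimated correlation (lowest adjusted p = 0.918), with 32 of 33 interferon-stimulated genes higher (32 adjusted over the list alone; adjusted p = 1.24e-09) and 10 of 17 sebaceous gland genes lower (10 adjusted over the list alone; adjusted p = 0.0483), each with an adjusted p = 0.918 with an estimated correlation. Against allogeneic isotype, a comparison of 2 control treatments, 6619 genes differed with water, 1789 higher and 4830 lower, of which 3307 had counts in 1 run only. None of the 16 genes named in every comparison passed there: Il36a was at -0.96 ± 0.63, Il1a at -0.88 ± 0.34 (adjusted p = 0.0581), Il33 at 1.08 ± 0.47 and Col1a1 at 0.45 ± 0.56.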

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

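The tests of the sequencing lane note, of an effect shared by all nintedanib libraries, of the Y-linked counts and of symbols with counts in 1 run were chosen after their results were seen, and those of hair growth genes, overlapping genes and other groupings of the libraries before.

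Hair follicle genes were higher with nintedanib, but 2 of 5 nintedanib libraries lay above the highest water library in their mean level, which argues against an effect shared by all of them. The share was 6.88% in nintedanib replicate 1, which has no sequencing lane note, so that note does not account for it. In replicates 1 and 3, 8 hair growth genes outside the list (Dlx3, Msx1, Wnt10b, Gprc5d, S100a3, Foxq1, Sox21 and Lhx2) were higher than in the other 3 by a mean of 4.35 on the log2 scale (SD 4.01 over genes), led by Gprc5d and S100a3. The difference ranged from 1.10 for Foxq1 to 10.8 for Gprc5d. Growing hair follicles in 2 of the skin pieces could give this. These libraries were singled out by their high hair follicle share, so the test cannot tell growing follicles from more follicle tissue. An effect of nintedanib on when follicles enter growth, in some animals only, stays open as untested.

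Genes on the Y chromosome had counts in 7 libraries and none in the other 14, which argues against spillover into all libraries. Spillover that reaches only some libraries would also leave zeros, so these counts cannot exclude it. Their sum was 4.41, 6.61, 2.73 and 3.86 CPM in syngeneic replicates 1 to 4, 15.2 CPM in anti-IL1RAP replicate 2, and 11.7 and 27.9 CPM in nintedanib replicates 2 and 4, where the limit allowed by 0 counts is 0.118 to 0.172 CPM. Xist, expressed from an inactive X chromosome, was at 340 ± 31.5 CPM in these libraries and 318 ± 69.7 CPM in the others, a ratio of 1.07, which argues against male recipients. Y-linked CPM followed Ptprc, a marker of blood cells, over the 7 libraries (Pearson r = 0.982, exact permutation p = 0.00198; Spearman rho = 0.857, exact permutation p = 0.0238; r = 0.817 without the 2 farthest libraries), as marrow-derived cells of male donors may give. The 4 lowest values are all syngeneic, so the relation also parts groups, and no group has enough libraries to test it alone.

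Between the water and isotype controls, 50.0% of the called genes had counts in 1 counting run only. Among called genes with counts in both runs, 60.2% overlap another gene in the reference annotation, against 32.2% of uncalled genes, a difference of 27.96 percentage points. The share was 74.5% of genes lower with water and 27.7% of genes higher. Both results may come from a different annotation or handling of overlapping genes in the 2 runs. The libraries with a sequencing lane note all lie in the second run, so the runs may also differ before counting, which was not tested. A difference between water and antibody controls stays open as well, since run and group cannot be told apart.

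Other groupings of the same libraries were tried for each count of changed genes. For allogeneic against syngeneic isotype and for water against syngeneic isotype, 1 of 35 splits, the real one, gave as many genes (4621 and 11078), and the highest other gave 0 in both. For water against isotype it was 1 of 35 (6619, highest other 10) and for anti-IL1RAP 1 of 35 (2204, highest other 0). A share of 1 of 35 is the smallest these splits can give. Among these 35, every other split mixes the 2 groups, which widens the spread and leaves few calls, so these splits cannot exclude chance. For nintedanib and for the difference of the treatment effects, only 100 of the possible splits were run. For nintedanib 2 of 100 splits gave as many as the real 1906. The other gave 2068 and put nintedanib replicate 4 with the 4 water libraries. The split that puts replicate 5 there was not run. The next highest splits gave 1089, 913 and 736. All of these kept nintedanib replicates 1 and 3 on the same side, though other such splits gave as few as 0. These counts point to a structure among the nintedanib libraries, whose source was not tested. For the difference of the treatment effects the real count is 0, which every split reaches by construction, so the splits say nothing about it.

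Counts of shifted lists separate less well from other groupings. The 20 lists of allogeneic against syngeneic isotype were reached by 1 of 35 splits (highest other 19). The 14 lists of water against syngeneic isotype were reached by 16 of 35 splits (highest other 19), the 17 of anti-IL1RAP by 4 of 35 (17), the 18 of nintedanib by 33 of 100 (26) and the 17 of the difference by 37 of 100 (26), so chance cannot be excluded for these.

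In 616 groups of 4 or 5 libraries, 47 held 1 library far from the others, where chance gives about 1 in 20 groups. Where the others had no counts, any reads set a library apart by construction. This holds for Stfa2 in syngeneic, Rxfp1, Trdv4 and Sphkap in allogeneic isotype, and Akr1d1, Csta3 and Stfa1 in anti-IL1RAP libraries. It also holds for AAdacl4fm3, Aadacl4, Serpina3j and Krt34 in water libraries. The 47 include these, so they cannot be set against 1 in 20. Syngeneic replicate 2 had mean log2 CPM of 2.29 for the cytotoxic list and -0.20 for the B cell list, and was at 7.31 for Ctss and -2.47 for Stfa2. Syngeneic replicate 3 had 6.81 for the sebaceous list, 1.71 for the melanocyte list, 6.49 for the immediate early list and 3.88 for Cartpt, and replicate 4 had -1.14 for Cxcl1. Allogeneic isotype replicate 1 stood apart at 0.94 for the gamma-delta T cell list, 3.83 for Cxcr2, -1.63 for Trdv4, -2.83 for Sphkap and -1.85 for Pvalb, a fast muscle gene at 7.25 or more in the other 3. Replicate 3 of that group was at 2.81 for Ly75, 5.12 for Tgfbr1 and 5.04 for Prx, and replicate 4 at 6.91 for Fn1, 1.60 for Ifi213, -2.67 for Rxfp1, 7.67 for Stat2 and 10.03 for Hrnr. Anti-IL1RAP replicate 1 was at -2.54 for Akr1d1 and 7.90 for Pmp22, replicate 2 at 5.96 for Il1rn, -2.99 for Csta3 and for Stfa1 and 3.30 for Il36b, replicate 3 at 5.04 for Il33 and replicate 4 at 6.30 for Dsc1. Water replicate 1 had 2.41 for the T cell list, -2.69 for AAdacl4fm3, -1.85 for Aadacl4, -2.21 for Serpina3j and 7.42 for Thbs1, and replicate 3 had -0.49 for Krt34. Water replicate 4 was at 4.91 for Cxcl2, 5.82 for Skil and 8.02 for Mmp9. Nintedanib replicate 1 was at 3.17 for Il36g, 3.52 for Oas2, 5.69 for Lce1a1 and 6.14 for Mitf, replicate 4 at 10.81 for Fn1, and replicate 5 at 4.92 for Aadacl4, -1.03 for Il24 and 7.70 for Krt6b.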

How the results depend on the processing

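The fits with symbols of both runs, libraries of 1 run, muscle or hair content as a covariate, or pairs of nintedanib libraries left out, and the score with isotype libraries divided, were chosen after the results were seen. Of 269 values of the counts and scores under other settings, 224 stayed on the same side of their threshold or within 1.5 times the count reported, and 79 of 6667 values of named genes changed direction, all but 1 of them in genes that were not called. Of the called named genes, 1559 of 1595 values kept their call for allogeneic against syngeneic isotype, 312 of 329 for water against syngeneic isotype, 1107 of 1196 for anti-IL1RAP and 1127 of 1521 for nintedanib. Of 100 simulated 2-fold changes, 40, 45 and 53 were recovered for allogeneic against syngeneic isotype, anti-IL1RAP and nintedanib. Genes that did not pass may therefore still differ by that much. The simulations gave a gene the same spread in all groups. With only its own groups in the fit, nintedanib had 94 calls in place of 1906, so 53 may overstate that comparison. Except where a reason is given, the cause was not tested.

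For allogeneic against syngeneic isotype, 10087 genes passed with both allogeneic controls together, which brings in the other counting run, and 2620 were over 2-fold, a stricter requirement. With symbols of both runs only, hence fewer genes, the count was 7325 for water against syngeneic isotype and 2822 for water against isotype. For anti-IL1RAP it was 7812 with both controls, 3664 with only libraries of its counting run and 1216 over 2-fold. Leaving out each library in turn gave 1284 to 2168, with 1320 without isotype replicate 4, 1353 without anti-IL1RAP replicate 3 and 1284 without anti-IL1RAP replicate 4. For nintedanib the count was 1190 with no filter, 94 with only its own groups or counting run in the fit, 6646 with both controls, 242 and 333 with only the libraries with or without the sequencing lane note, 863 over 2-fold and 3046 with DESeq2. It was 1225 without nintedanib replicates 1 and 3 and 3197 without replicates 2 and 4. Leaving out single libraries gave 782 to 2794, with 1067, 1213 and 782 without water replicates 2, 3 and 4 and 1235 and 1231 without nintedanib replicates 1 and 3. For the difference of the effects, 0 with all libraries, the count was 1 with hair content as a covariate, 4 without nintedanib replicates 1 and 3, 687 without replicates 2 and 4 and 364 with DESeq2. It ranged from 0 to 7 when single libraries were left out, with 2, 7 and 2 without nintedanib replicates 1, 2 and 4.

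With an estimated correlation, 0 lists shifted in allogeneic against syngeneic isotype, 0 in water against syngeneic isotype, 0 for anti-IL1RAP, 0 for nintedanib and 0 for the difference, where the preset correlation gave 20, 14, 17, 18 and 17. Fry called 17 lists for allogeneic against syngeneic isotype and 17 for water against syngeneic isotype. It called 7 lists for anti-IL1RAP, 11 for nintedanib and 1 for the difference. For the difference, 11 lists shifted with hair content as a covariate and 10 without nintedanib replicates 1 and 3. The anti-IL1RAP score with isotype libraries divided was -3.13.

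Libraries with the same replicate number did not deviate together: 6 of 40 pairs had a correlation over 0.1 (range -0.408 to 0.347), and 5 of 21 libraries correlated best with their own number, so the numbers do not pair the samples. With the replicate number as a block the counts were 4498 for allogeneic against syngeneic isotype, 10995 for water against syngeneic isotype, 6570 for water against isotype, 2012 for anti-IL1RAP, 2130 for nintedanib and 0 for the difference, and the block changed no count by over 1.5 times. The blocked scores were -0.152 and -2.31 with an exact permutation p = 0.125, the smallest that 4 pairs allow. Pdgfrb with nintedanib was at -0.21 with the block and -0.13 with the block taken from the number in the sample descriptions, under which Cxcl1 with anti-IL1RAP was at 0.032.

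Among values that changed direction, both controls together gave 0.15 for Fn1 in allogeneic against syngeneic isotype, -0.23 for Il33 in water against syngeneic isotype, -0.17 for Il33, 0.063 for Cxcl1 and -0.12 for Fn1 with anti-IL1RAP, and 0.14 for Il33 with nintedanib. A term for the lane note gave 0.11 for Acta2 in water against syngeneic isotype and -0.059 for Pdgfrb with nintedanib. Only libraries with the note gave 0.71 for Il33 and -0.65 for Fn1 with nintedanib, and only those without it 0.079 for Il1rap, -0.077 for Pdgfra and -0.67 for Pdgfrb. Muscle content as a covariate gave 0.24 for Cxcl1 in water against isotype, 0.51 for Cxcl1 with anti-IL1RAP and -0.018 for Fn1 in the difference. Hair content as a covariate gave -0.057 (Krt34, nintedanib against allogeneic water), by construction since Krt34 is in that list, and -0.22 for Fn1 in the difference. For the difference, leaving out nintedanib replicates 1 and 3 gave -0.20 for Il6, -0.47 for Fn1 and -0.051 (Pdgfrb, anti-IL1RAP effect against nintedanib effect), and leaving out replicates 2 and 4 gave -0.17 for Col1a1, and -0.90 for Fn1 with nintedanib. RLE size factors and DESeq2 each gave -0.0047 (Fn1, anti-IL1RAP effect against nintedanib effect).

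Leaving out single libraries gave these ranges of log2 fold change for genes whose direction changed. In allogeneic against syngeneic isotype they were -0.36 to 0.048 for Fn1 and -0.41 to 0.20 for Acta2, and in water against syngeneic isotype -0.32 to 0.59 for Il33 and -0.21 to 0.12 for Acta2. In water against isotype they were -0.69 to 0.48 for Cxcl1, -0.078 to 0.24 for Il1rap, -0.85 to 1.37 for Il1b, -0.26 to 0.067 for Il1rn, -0.47 to 0.71 for Il6, -0.090 to 0.69 for Col1a2, -0.24 to 0.37 (Acta2, allogeneic water against allogeneic isotype) and -0.33 to 0.42 for Pdgfra. With anti-IL1RAP they were -0.62 to 0.75 for Cxcl1 and -0.027 to 0.38 (Fn1, anti-IL1RAP against allogeneic isotype). With nintedanib they were -0.68 to 0.23 for Il33, -0.95 to 0.60 for Fn1, -0.18 to 0.25 for Pdgfrb and -0.029 to 0.30 for Acta2. In the difference they were -0.27 to 0.94 for Il6, -0.093 to 0.84 (Col1a1, anti-IL1RAP effect against nintedanib effect), -0.37 to 1.17 for Fn1, -0.092 to 2.12 (Il1b, anti-IL1RAP effect against nintedanib effect) and -0.017 to 0.57 (Acta2, anti-IL1RAP effect against nintedanib effect).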

Other observations

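Leaving out nintedanib replicates 1 and 3, or 2 and 4, was chosen after its result was seen.

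With all libraries, edgeR called 0 genes (2495 with an unadjusted p under 0.05) and DESeq2 364 for the difference between the anti-IL1RAP and nintedanib effects, and edgeR called 687 without nintedanib replicates 2 and 4. The list shifts below depend on the preset correlation. Their number was reached in 37 of 100 groupings of the libraries, the real one included. Schwann cell genes were more positive for anti-IL1RAP (7 of 10 adjusted over the list alone; adjusted p = 4.59e-06), as were endothelial genes (0 of 16 called; adjusted p = 7.83e-05), mast cell genes (0 of 11; adjusted p = 0.000478) and the receptors inhibited by nintedanib with their ligands (0 of 25; adjusted p = 0.00132). Cell cycle genes were more negative (0 of 26; adjusted p = 0.000527), as were hair follicle genes (20 of 22 adjusted over the list alone; adjusted p = 0.000581) and melanocyte genes (0 of 8; adjusted p = 0.0112). With an estimated correlation each of these had an adjusted p = 0.666 or more. With nintedanib replicates 1 and 3 left out, the libraries with high hair follicle shares, 10 lists shifted in place of 17 (anti-IL1RAP effect against nintedanib effect). The Schwann cell (adjusted p = 5.25e-06), endothelial (adjusted p = 0.0354) and mast cell lists (adjusted p = 0.0155) were among them. The cell cycle (adjusted p = 0.616), hair follicle (adjusted p = 0.604), melanocyte (adjusted p = 0.340) and receptor lists (adjusted p = 0.108) were not.

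The Schwann cell list averaged 5.24 ± 0.37 log2 CPM in syngeneic skin, 4.49 ± 0.11 in allogeneic isotype, 5.62 ± 0.16 with anti-IL1RAP, 4.73 ± 0.18 in water and 4.42 ± 0.65 with nintedanib (SD). The cell cycle list averaged 4.55 ± 0.36 in allogeneic isotype and 4.04 ± 0.39 with anti-IL1RAP, against 4.16 ± 0.30 in water and 4.48 ± 1.18 with nintedanib. That higher mean comes from nintedanib replicates 1 and 3 (5.56 and 5.69), and the other 3 were at 2.84, 4.25 and 4.06. Without replicates 1 and 3 the list tested downward (nintedanib against allogeneic water, adjusted p = 0.0293, 0 of 26 called, not tested at an estimated correlation). That direction rests on replicate 2, since replicates 4 and 5 lie within the water range of 3.75 to 4.47, so no direction is settled.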
